A study of Mus musculus with 6 samples.

How the data were processed

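Total RNA came from dorsal and ventral aortic tissue of C57BL/6 mouse embryos, frozen unfixed, sectioned and cut by laser microdissection. Per the labels' protocols, picogram amounts of RNA were reverse transcribed and amplified by the single-primer isothermal method of the NuGEN Ovation Pico kit, biotin labelled and hybridised to Affymetrix Mouse Gene ST arrays. Such amplification can distort the ratio of weak to strong transcripts, and the arrays compress fold changes of genes near background. The deposited values are log2 expression levels, 1 per probe set and array, and the submitters' processing notes name Affymetrix Expression Console and RMA, which corrects background, applies quantile normalization between arrays and summarises probes. Versions, the probe grouping and a genome build are not given in the sources used here. Rows are numbered by Entrez gene identifier per the platform table, so that probes had been grouped by gene. The array medians were 4.49 to 4.55, and the correlation between arrays over all probe sets was 0.956 to 0.976, across genes, which are not independent replicates.

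Of 24973 probe sets, 24015 had 1 gene symbol in the platform table, 0 had several and 958 are unnamed here. Neighbouring genes were read from a RefSeq gene table of a mouse assembly, used for names and gene order only. The 6 arrays fall into 3 dorsal and 3 ventral by the tissue in their labels, and the replicate numbers come from the titles. The main comparison was ventral minus dorsal, fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes without a trend), with the replicate number as a fixed block, two-sided tests and Benjamini-Hochberg adjustment over the 12028 genes with a symbol and a mean over the 6 arrays at or above the median of all probe sets (4.52). The threshold was an adjusted p of 0.05. The median standard deviation was 0.220 over dorsal and 0.233 over ventral arrays, the median standard error of a log2 fold change was 0.196, and each test had 6.41 degrees of freedom, 4.41 of them from the prior. All adjusted p of single genes come from limma. Standard errors are those of the moderated fit, and SD is over 3 arrays. Where the mean of a tissue lies below the filter level, a printed fold is that of the deposited values and gives no exact ratio of transcript.

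The block was used because the labels say that the dorsal and the ventral tissue came from the same embryos. They do not say outright that a replicate number marks an embryo. The deviations of same-numbered arrays from their tissue means correlated by 0.0992, 0.0763 and 0.226 for numbers 1, 2 and 3, not all above 0.1. Those of differently numbered arrays ran from −0.153 to 0.0805, and dorsal 2 correlated more with ventral 1 (0.0805) than with ventral 2. These correlations support the pairing only weakly. The replicate 3 arrays shared a stronger signal, with 25 genes at least 2 (log2) higher in both tissues than on replicates 1 and 2, and 0 as far below. That covers number 3 only and does not tell a shared embryo from a shared batch. The consensus within-number correlation was 0.0557. Y-linked transcripts were high and Xist low on all 6 arrays (Eif2s3y 7.74 to 8.51, Xist 3.17 to 3.52), so sex-linked genes gave no information on pairing. For each gene named in the text whose call over all genes or over a list alone changed without the block, the adjusted p without it is printed. Of 80 calls made over a list alone, 57 also passed without the block. If some arrays pooled sections of several embryos, p-values measure the spread between such pools.

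There were 28 gene lists of cell types, pathways and technical signs, 26 of which were tested. A list of mitochondrial transcripts had no member named in the platform table, and a list of sex-linked genes served only to check the pairing. Of 597 list entries 552 were named in the table, and 401 different list genes were tested, 11 of which passed. Lists were tested with limma's camera at a preset correlation of 0.01, with at least 5 tested members and Benjamini-Hochberg adjustment over the 26 lists. Camera with an estimated correlation and the directional test of fry were run beside it, and each called 0 lists. With an estimated correlation, camera's test rests on the residual degrees of freedom, 2 in the main fit, and has little power. For the hedgehog list the estimate was 0.00239, below the preset, yet camera's unadjusted p rose from 0.00241 to 0.0850. A call missing there therefore does not show that correlation between genes removes it. The mixed test of fry, which ignores direction, passed for some lists, with or without a camera call. Among them were splanchnic and gut mesenchyme, hematopoietic stem and progenitor, and retinoic acid and FGF genes (adjusted p = 0.0249 each), and Wnt genes (0.0316). The genes named were, among those past the threshold with the same sign in all 3 pairs, the 15 with the highest and the 15 with the lowest log2 fold change, leaving out predicted genes, clone names and small RNAs, together with members of the lists. The lists, the naming rule, the design and all alternatives except 2 were fixed before the data were examined.

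Alternatives were no block, a random block, leaving out each pair, leaving out each array without the block, no brightness filter and a filter at the 75th percentile. Others were a median shift, quantile normalization and cyclic loess of the tested genes, and an intensity trend together with robust estimation of the prior. Array weights, averaging of probe sets, other thresholds and all probe sets were run as well. The fit was tested on simulated data for this comparison with 12028 genes, 200 of them changed, in 10 simulations. It recovered 19.2% of genes changed by 1 on the log2 scale, 94.0% of those changed by 2, 99.0% of those changed by 3 and 99.8% of those changed by 4, and 4.70% of calls were false. Differences of 2-fold were therefore mostly missed with this number of arrays. The simulated errors were independent between genes, with SDs drawn from the fitted prior and small pair effects. In the real arrays the estimated correlation within a list reached 0.88 (sympathoadrenal cells), so these percentages do not measure the false calls made here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Other embryonic stages of the study were not analysed here.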

Results

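Gene expression was measured in embryonic tissue taken from either side of the mouse aorta at embryonic day 11.5, a stage at which hematopoietic stem cells (HSCs) arise in the aorta-gonad-mesonephros region. Dorsal tissue came from the space separating the notochord from the aortic roof, and ventral tissue from directly below the vessel. Both were cut from cryosections of C57BL/6 embryos by laser microdissection, and their RNA was amplified and hybridised to Affymetrix whole-transcript arrays. Each tissue was profiled on 3 arrays, labelled as biological replicates 1 to 3, and the number of arrays limits the precision of every value given here. The series concerns the tissue beneath the aorta as a niche for HSCs, so the comparison asks which genes differ between the ventral and the dorsal side. Of 24973 probe sets, 12028 named genes passed a brightness filter at the median level of 4.52 (log2) and were tested.

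Genes higher in ventral tissue included Tcf21, Gata6, Hlx and Zfpm2, and genes higher in dorsal tissue included Pax1, Col2a1, Chad, Clec3a and Foxf2. In limma, 62 genes passed an adjusted p of 0.05, with 37 higher in ventral and 25 higher in dorsal tissue. The split depended on the pair: 54 and 21 genes passed without replicate 1, 35 and 18 without replicate 2, and 22 and 26 without replicate 3, so the ventral majority did not hold there. Each of the 62 differed in the same direction in all 3 same-numbered pairs, and the smallest difference among them was 2.50-fold, with a median of 4.26-fold. The dorsal and ventral arrays of all 62 genes did not overlap, which held for 15.4% of all genes tested, where chance gives 10%. The first principal component held 32.3% of the variance and separated the tissues, with dorsal arrays at −23.0 to −21.8 and ventral arrays at 19.9 to 24.9. Without the replicate number as a block 59 genes passed, 45 of them shared. Without the brightness filter 10 genes passed, 9 of them shared.

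Among genes higher in ventral tissue, the greatest differences were in a pair of segments of the T-cell receptor alpha locus. Traj11, a joining segment, averaged 9.94 ± 1.01 (SD, n = 3) in ventral and 3.70 ± 0.76 (n = 3) in dorsal tissue, a log2 fold change of 6.24 ± 0.19 (SE; adjusted p = 0.000233). Trac, the constant region of the same locus, averaged 9.81 ± 1.23 in ventral and 3.58 ± 0.27 in dorsal tissue, a log2 fold change of 6.23 ± 0.36 (adjusted p = 0.00336). Of the other segments of the locus, only 6 of 56 J segments and 6 of 45 V segments were above the brightness filter and tested, and none passed. Without the filter none passed either, but most lie at low levels, where a difference could be missed. Traj18 was the highest of them (1.77 ± 0.82). The constant regions of the beta locus, Trbc1 and Trbc2, differed by 0.07 each. Tcf21, a basic helix-loop-helix factor of visceral mesenchyme, was 26.0-fold higher in ventral tissue (log2 fold change 4.70 ± 0.29, adjusted p = 0.00347). Gata6, a zinc-finger factor of endoderm and visceral mesoderm, was 9.13-fold higher (3.19 ± 0.19, adjusted p = 0.00336), and Zfpm2, a cofactor of GATA proteins, was 4.85-fold higher (2.28 ± 0.22, adjusted p = 0.0211). Iigp1, an interferon-inducible GTPase, averaged 8.39 ± 0.31 in ventral and 4.36 ± 0.60 in dorsal tissue (log2 fold change 4.03 ± 0.20, adjusted p = 0.00286). Without the block the standard errors of Traj11, Trac, Tcf21, Gata6, Zfpm2 and Iigp1 were larger, at 0.54, 0.53, 0.61, 0.35, 0.30 and 0.31. All of them still passed, with adjusted p from 0.00397 (Iigp1) to 0.0251 (Zfpm2).

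**Figure D1:**
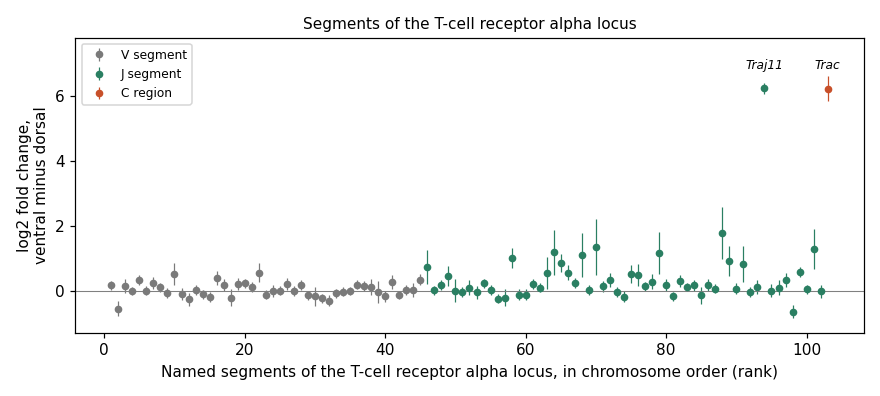
Log2 fold change, ventral minus dorsal (vertical axis), of 45 V segments, 57 J segments and the C region of the T-cell receptor alpha locus, ranked by chromosome order (horizontal axis, no unit), with points for estimates and bars for standard errors over 3 arrays per tissue, fitted without the brightness filter. Traj11 and Trac stand above 6, while Traj18, the next highest, lies at 1.77.

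Further genes were higher in ventral tissue. Ntrk3, the receptor of neurotrophin-3, had a log2 fold change of 2.44 ± 0.25, and Unc5c, a netrin receptor, one of 2.51 ± 0.29. The proteoglycan Dcn (2.14 ± 0.26), the matrix protein Ecm1 (2.47 ± 0.31) and the secreted metalloprotease Adamts9 (2.10 ± 0.23) were higher as well. The group also held Tmtc2 (3.02 ± 0.20), Gask1b (2.75 ± 0.29), the cadherin Cdh18 (2.11 ± 0.19) and Rgs5, a regulator of G-protein signalling expressed in pericytes (2.18 ± 0.24). Their adjusted p ran from 0.00461 for Tmtc2 to 0.0358 for Ecm1. Without the block, Unc5c (adjusted p = 0.0650) and Rgs5 (0.0732) did not pass, and over all alternatives the adjusted p of these 2 genes ran from 0.0124 to 0.243. Without replicate 3, Rgs5 (adjusted p = 0.0675), Dcn (0.0504) and Adamts9 (0.0594) did not pass, and neither did Adamts9 without replicate 1 (0.0510).

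Among genes higher in dorsal tissue, the greatest differences were in the serum amyloid A genes, which are near-identical neighbours whose probes can share signal. Saa2 averaged 7.66 ± 1.36 (SD, n = 3) in dorsal and 3.08 ± 1.21 (n = 3) in ventral tissue, a log2 fold change of −4.59 ± 0.37 (adjusted p = 0.0114). Saa1 had a log2 fold change of −4.10 ± 0.47 (adjusted p = 0.0305). Pax1, a paired-box factor of the sclerotome, was 6.08-fold higher in dorsal tissue (−2.60 ± 0.24, adjusted p = 0.0183), and the long noncoding RNA AI646519, which neighbours it, was 10.4-fold higher (−3.38 ± 0.19, adjusted p = 0.00336). The cartilage matrix gene Chad (−2.32 ± 0.21) and the cartilage lectin gene Clec3a (−2.09 ± 0.21) differed in the same direction. So did Foxf2, a forkhead factor (−2.71 ± 0.25), the adhesion receptor Adgrg6 (−3.34 ± 0.36) and Lrig1, which restrains epidermal growth factor receptor signalling (−2.30 ± 0.18).

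Further genes higher in dorsal tissue were Plod2, a lysyl hydroxylase that modifies collagen (−2.11 ± 0.25), the hyaluronan-binding Tnfaip6 (−2.09 ± 0.25), the ubiquitin ligase Wwp2 (−2.01 ± 0.25), the T-box factor Tbx1 (−1.86 ± 0.25), Ebf3 (−1.83 ± 0.21) and Rtl3 (−2.15 ± 0.26). Without the block 6 of the 15 dorsal genes chosen by the naming rule lost their calls, namely Saa2 (adjusted p = 0.0603), Foxf2 (0.0742), Tbx1 (0.0650), Wwp2 (0.0992), Tnfaip6 (0.195) and Rtl3 (0.249). Over all alternatives the adjusted p of these 6 genes ran from 0.00308 to 0.522. Plod2, Wwp2, Tbx1 and Rtl3 did not pass without replicate 1 (0.0608, 0.0554, 0.0842 and 0.0601) or without replicate 2 (0.0532, 0.0601, 0.0876 and 0.0557). Tnfaip6 and Ebf3 did not pass without replicate 2 (0.0557 for both) or without replicate 3 (0.0831 and 0.0761). Of the 30 genes described so far by the naming rule, 21 passed without each pair in turn, and 8 also passed without the brightness filter (Traj11, Trac, Tcf21, Iigp1, Gata6, Tmtc2, AI646519 and Lrig1).

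**Figure D2:**
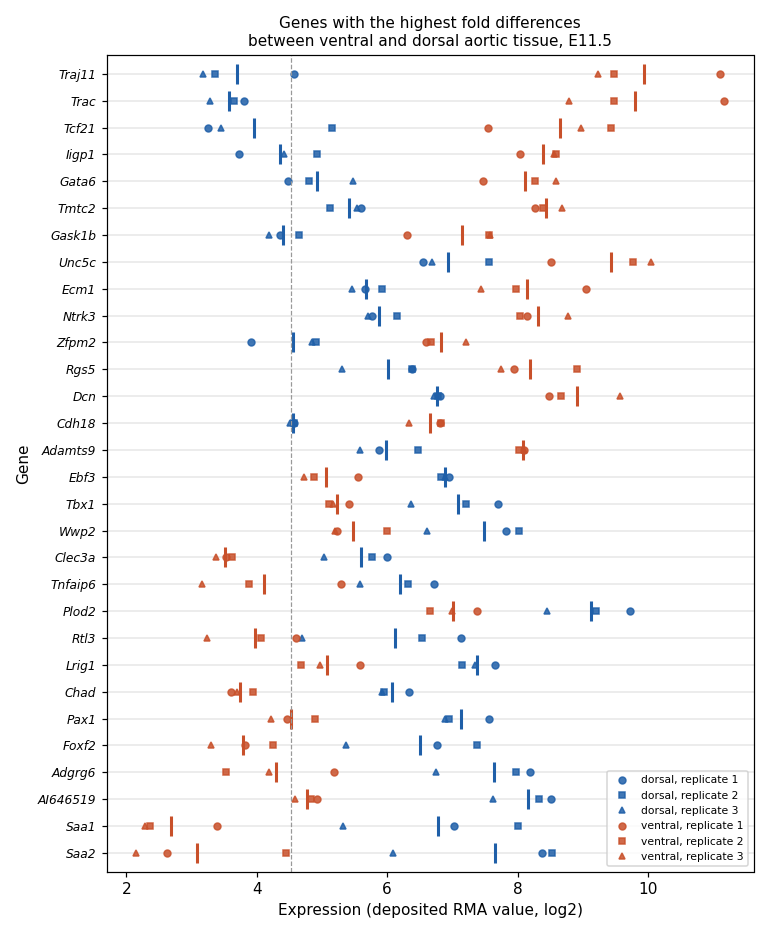
Deposited expression level (log2, horizontal axis) of the 30 named genes (vertical axis) on each array, blue for dorsal and orange for ventral tissue, with marker shape giving the replicate, vertical ticks the mean of 3 arrays and the dashed line the brightness filter at 4.52. The ventral and dorsal arrays of every gene shown are apart, from Traj11 (log2 fold change 6.24) to Saa2 (−4.59).

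Of 16 tested sclerotome and early cartilage genes, 12 had negative log2 fold changes, and Pax1 and Col2a1 (−1.75 ± 0.19, adjusted p = 0.0258) passed over all genes. Adjusted over the list alone 8 of the 16 passed, all higher in dorsal tissue, among them Pax9 (−2.69 ± 0.51) and Sox9 (−0.89 ± 0.21), and the same 8 passed without the block. The list was called lower in ventral tissue by camera (adjusted p = 2.42e-06; adjusted p = 0.492 with an estimated correlation). Col2a1 did not pass without replicate 1 (0.0513) or replicate 2 (0.0557). In the hedgehog list, 10 of 17 genes had negative and 7 positive log2 fold changes, 1 passed over all genes (Foxf2, not without the block) and 5 when adjusted over the list alone, all higher in dorsal tissue, including the pathway targets Ptch1 (−1.63 ± 0.24) and Gli1 (−1.20 ± 0.22). Of these 5, 3 passed over the list without the block, namely Ptch1, Foxf2 and Nkx3-2, and Gli1 did not (adjusted p = 0.142 over the list). Foxf2 and Nkx3-2 are also on the splanchnic list, and Nkx3-2 is among the sclerotome calls, so these lists are not separate evidence. Camera called the hedgehog list lower in ventral tissue (adjusted p = 0.00569, and 0.492 with an estimated correlation).

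Of 9 tested genes of the gonadal ridge and coelomic epithelium, Tcf21 passed over all genes, and adjusted over the list alone 5 were higher in ventral tissue, including Wt1 (1.29 ± 0.20), Upk3b (1.18 ± 0.17) and Gata4 (1.78 ± 0.34), and 1 was higher in dorsal tissue, Lhx2 (−0.87 ± 0.31; adjusted p = 0.0580 over the list without the block). Among 16 splanchnic and gut mesenchyme genes, Gata6 and the homeobox gene Hlx (2.00 ± 0.19, adjusted p = 0.0183) were higher in ventral tissue and Foxf2 was higher in dorsal tissue, with 6 and 2 genes when adjusted over the list alone, with and without the block. All 15 smooth muscle and pericyte genes had positive log2 fold changes. Rgs5 passed over all genes with the block and not without it (adjusted p = 0.0732), and adjusted over the list alone 4 passed, including the contractile genes Cnn1 (2.79 ± 0.50) and Acta2 (1.47 ± 0.34; adjusted p = 0.142 over the list without the block). In the extracellular matrix list, Dcn passed among 41 genes, and adjusted over the list alone 9 were higher in ventral tissue, including Postn (1.77 ± 0.26) and Col1a1 (1.15 ± 0.18), while Ogn (−1.19 ± 0.20) and Thbs2 (−0.73 ± 0.18) were higher in dorsal tissue. Of these 11 matrix genes 9 passed without the block, including the 4 just named, and 3 others were added. Camera called these 4 lists higher in ventral tissue, with adjusted p of 4.65e-05, 0.00234, 9.28e-08 and 2.42e-06 in the order given (adjusted p = 0.492 with an estimated correlation for each). The mean level of a list on an array was taken relative to each gene's mean over the 6 arrays. For splanchnic and gut mesenchyme genes it overlapped between the tissues, with ventral 1 (−0.273) below dorsal 2 (−0.0479).

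All 13 erythroid genes had negative log2 fold changes (Alas2, −0.93 ± 0.26; Klf1, −0.61 ± 0.18), with a median of −0.50 and none passing over all genes or over the list alone. Of 16 macrophage genes 15 had positive values, with a median of 0.35, and Lyve1 (0.79 ± 0.17) passed when adjusted over the list alone, though not without the block (0.191). Of 21 endothelial genes none passed over all genes, while adjusted over the list alone Kdr (1.00 ± 0.20), Cldn5 (0.70 ± 0.18) and Sox18 (0.70 ± 0.19) were higher in ventral tissue and Fli1 (−0.80 ± 0.21) in dorsal tissue, as they were without the block, where 1 more passed. Camera called the erythroid list lower (adjusted p = 4.65e-05) and the macrophage (0.000230) and endothelial lists (0.000269) higher in ventral tissue (adjusted p = 0.492 with an estimated correlation for each). Without the block, the macrophage call was lost without dorsal 3 (adjusted p = 0.144) or ventral 1 (0.0946). The mean level of macrophage genes overlapped between the tissues, with dorsal 2 (0.134) above ventral 2 (0.0441) and ventral 3 (0.0206). That of endothelial genes overlapped too, with dorsal 2 (0.216) above ventral 1 (−0.0319). The list of hematopoietic stem and progenitor genes was not called by camera (adjusted p = 0.220), while the mixed test of fry, which ignores direction, gave 0.0249. None of its 15 genes passed over all genes, and adjusted over the list alone Kit (1.01 ± 0.19) was higher in ventral tissue with and without the block. Mecom (−1.35 ± 0.19) and Myb (−1.03 ± 0.18) passed over the list, on the dorsal side, only with the block. Without it their standard errors were 0.51 and 0.31 and their adjusted p over the list 0.0866 and 0.0676. Runx1, which is required for HSC formation, had a log2 fold change of 0.96 ± 0.33 (adjusted p = 0.354).

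Secreted factors were compared because the question concerns a niche. Among 20 HSC niche factors none passed over all genes, and Tgfb2 (1.30 ± 0.25) passed when adjusted over the list alone, with and without the block. Igf1 had a log2 fold change of 1.42 ± 0.35, Kitl one of 0.57 ± 0.40 and Cxcl12 one of −0.05 ± 0.26, none of them passing. The list was called higher in ventral tissue (camera, adjusted p = 0.0252; adjusted p = 0.492 with an estimated correlation), and was not called without replicate 3 (adjusted p = 0.242). Of 24 BMP and TGF-beta pathway genes none passed over all genes, while adjusted over the list alone 7 were higher in ventral tissue, among them Tgfb2, the BMP antagonist Chrdl1 (1.23 ± 0.25) and the inhibitors Bambi (0.93 ± 0.21) and Smad7 (0.76 ± 0.17). These 4 were the ones that also passed without the block. Camera called that list higher in ventral tissue (adjusted p = 0.000255; adjusted p = 0.492 with an estimated correlation). In the Wnt list, the secreted antagonist Frzb (1.89 ± 0.18, adjusted p = 0.0208) was higher in ventral and the agonist Rspo2 (−1.75 ± 0.24, adjusted p = 0.0468; 0.127 without the block) in dorsal tissue, and the list of 23 genes was not called (adjusted p = 0.871). Frzb did not pass without replicate 3 (0.0507), nor Rspo2 without replicate 1 (0.0842) or replicate 2 (0.0915).

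**Figure D3:**
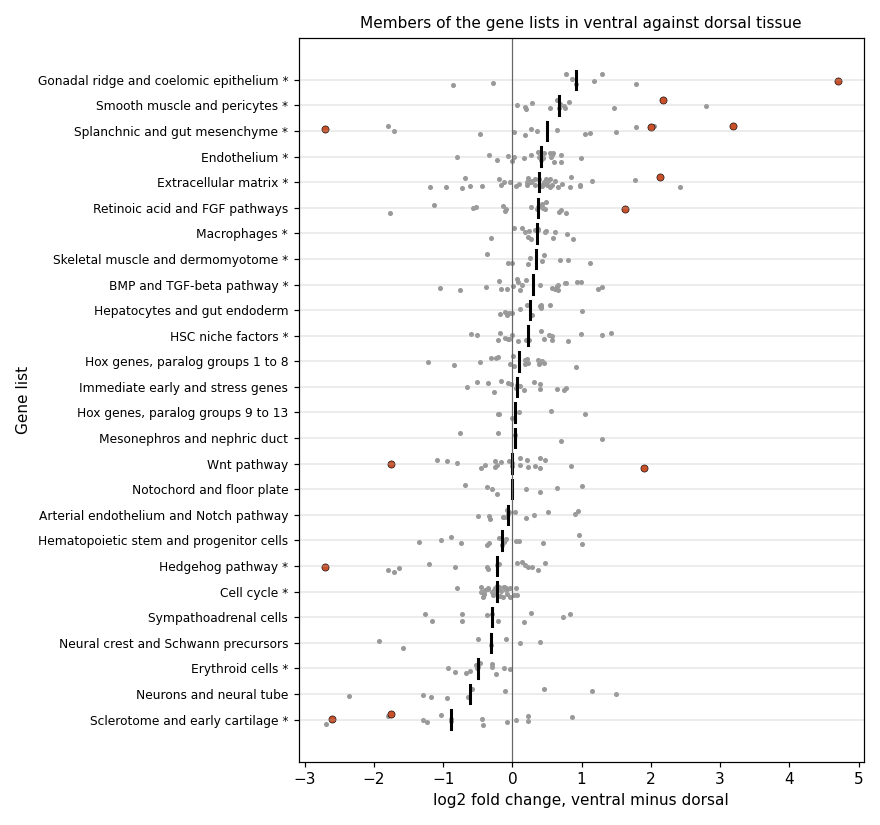
Log2 fold change, ventral minus dorsal (horizontal axis), of every tested member of the 26 gene lists (vertical axis), with black bars for list medians, orange points for genes past an adjusted p of 0.05 over all genes, and an asterisk for the 13 lists called by camera with its preset correlation. Medians ran from −0.89 for sclerotome to 0.91 for gonadal ridge and coelomic epithelium, and 0 lists were called with an estimated correlation.

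Camera also called the cell cycle list lower in ventral tissue (28 of 31 genes negative, median −0.23, adjusted p = 0.000440; adjusted p = 0.492 with an estimated correlation), with no gene passing and no call without replicate 3 (adjusted p = 0.155). The skeletal muscle and dermomyotome list was called higher by camera (adjusted p = 0.0164, and 0.492 with an estimated correlation), with no list call without replicate 1 (adjusted p = 0.582). Des (1.12 ± 0.18) passed when adjusted over the list alone (0.149 without the block). The mean level of this list overlapped between the tissues, with ventral 3 (−0.142) below dorsal 2 (−0.119) and dorsal 3 (−0.0460). Lists that camera did not call were neurons and neural tube (adjusted p = 0.0541), hepatocytes and gut endoderm (0.0937), retinoic acid and FGF pathways (0.0976), neural crest and Schwann precursors (0.128), late Hox genes (0.217), mesonephros (0.382), immediate early and stress genes (0.529), early Hox genes and arterial and Notch genes (0.569 for both), sympathoadrenal cells (0.628) and notochord (0.703). In the retinoic acid list, Aldh1a1, a retinaldehyde dehydrogenase, was higher in ventral tissue (1.62 ± 0.18, adjusted p = 0.0258), and did not pass without replicate 1 (0.0521) or replicate 3 (0.0750). Under some alternatives camera with its preset correlation called further lists, while with an estimated correlation it called 0 lists under every alternative run for lists (lowest adjusted p 0.190). Estimates from so few arrays are rough, and with 1 to 4 residual degrees of freedom this test had little power to call any list. The further calls made with the preset correlation carry little weight. The neuron list was called lower in ventral tissue after the arrays were shifted to the same median (adjusted p = 0.0446), after cyclic loess (0.0475), without the brightness filter (0.00974) and without replicate 2 (0.0173). Neural crest was called lower without the filter (0.0439), without replicate 1 (0.0385) and without replicate 3 (0.0320). Hepatocytes and gut endoderm were called higher without replicate 1 (0.0112) and without replicate 2 (0.000943), and lower without the block and without ventral 3 (0.0258). Without replicate 3 the retinoic acid list was called higher (0.0328) and the early Hox list lower (0.0384). Sympathoadrenal cells were called in opposite directions, higher in ventral tissue without replicate 1 (0.0377) and lower without replicate 3 (0.000381). The arterial and notochord lists had negative medians (−0.06 and −0.01) but positive means (0.08 for both). Genes abundant in liver and yolk sac stood apart on both replicate 3 arrays, where Afp was at 10.99 in dorsal and 11.63 in ventral tissue against 3.64 to 4.82 on the other 4 arrays. Without replicate 3, 48 genes passed between the tissues, 37 of them among the 62.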

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

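Both results here came from probe sets that the main comparison left out. Of 459 probe sets that are unnamed here and passed the brightness filter, 2 differed between ventral and dorsal tissue when all probe sets were tested together (limma, adjusted p under 0.05). They stand here because they lie outside the set of named genes, and no gene is given for them. Among named genes below the brightness filter, 1 passed when the filter was dropped, namely Zfp804a, chosen after its values were seen. Zfp804a, a zinc-finger gene, had a log2 fold change of 2.47 ± 0.13 (SE, adjusted p = 0.0197) in favour of ventral tissue, at a mean level of 3.61 over the 6 arrays. No explanation was tested for either result.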

How the results depend on the processing

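All 62 genes kept their direction under every alternative in which they were tested. Since each had the same sign in all 3 pairs and arrays that did not overlap, leaving out pairs or arrays could not reverse it. The kept direction therefore says little about stability. The count of 62 stayed between 54 and 92 with a random block, a stricter filter, renormalization, a trend and robust prior, array weights and all probe sets. The genes behind the count changed in part. With a random block 65 genes passed, 47 of them shared. With the stricter filter 54 passed, 31 of them shared, and only these 31 of the 62 were tested there. Averaging probe sets changed nothing, since no tested gene had more than 1, and says nothing about stability. Without the replicate block 59 genes passed (36 higher in ventral, 23 higher in dorsal), 45 of them shared. Leaving out pair 1, 2 or 3 gave 75 (54 ventral, 21 dorsal), 53 (35 and 18) and 48 genes (22 and 26), so the ventral majority did not hold without replicate 3, and 28 of the 62 passed without each pair in turn, 23 of these also without the block.

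Without the brightness filter 10 genes passed among 24011, 8 of them higher in ventral tissue. With a trend and robust estimation of the prior as well, an alternative chosen after seeing the data, 25 passed, 21 of them shared. Part of the loss came from the prior, whose degrees of freedom fell from 4.41 to 3.28, since with that prior 28 genes passed when adjusted over the filtered genes only, and the rest from the larger number of tests. The filter at the 75th percentile left 6026 genes, 54 of which passed, with 72.2% of calls higher in ventral tissue against 59.7%. Looser thresholds gave 131 genes (adjusted p of 0.10) and 883 genes (unadjusted p of 0.05 with at least 1.5-fold).

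Without the block, leaving out 1 array moved the count from 12 to 104. It was 12, 23 and 40 without dorsal 1, 2 and 3, and 104, 13 and 18 without ventral 1, 2 and 3. The cause was not tested.

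Camera called 13 lists with and without the block and 15 without each pair in turn. With an estimated correlation it called 0, there and under every alternative run for lists (the latter chosen after seeing the data). That test had little power with so few residual degrees of freedom. The directional test of fry called 0, while its mixed test, which ignores direction, passed for some lists, such as gonadal ridge and Wnt (adjusted p = 0.0316 for both). None of the 13 lists called by camera reversed. Among the other lists, sympathoadrenal cells were called higher in ventral tissue without replicate 1 and lower without replicate 3, and hepatocytes higher without replicate 1 or 2 and lower without the block and ventral 3. Of 80 calls over a list alone, 57 held without the block. Calls lost were skeletal muscle without replicate 1 or the filter, HSC niche factors without replicate 3 or the filter, and cell cycle without replicate 3, and some lists also lost a call when 1 array was left out without the block. The random block was not run for lists.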

Other observations

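The lists behind the tests in this part, and the patterns they address, were chosen only after the gene results were seen. Bootstrap intervals in this part resample the genes of a list, not the arrays, and genes of a list can move together. They measure the spread between genes and not the uncertainty over 3 arrays per tissue. Those for replicate 3 compare it with the mean of replicates 1 and 2 within each tissue. Beyond the genes described so far, those past the threshold and higher in ventral tissue included the axon guidance ligand Slit2 (log2 fold change 2.04 ± 0.26, SE, 3 arrays per tissue; adjusted p = 0.0404, and 0.0650 without the block), the cytochrome P450 gene Cyp1b1 (2.07 ± 0.24, adjusted p = 0.0319, and 0.0572 without the block), the protocadherin Pcdh7 (1.99 ± 0.22, adjusted p = 0.0258), the basement membrane gene Fras1 (1.71 ± 0.19, adjusted p = 0.0258) and the phosphodiesterase Pde5a (1.46 ± 0.17, adjusted p = 0.0322). Each of these 5 genes lost its call without at least 1 of the 3 pairs, with adjusted p from 0.0557 to 0.0841. Genes higher in dorsal tissue included the kinesin Kif21a (−1.73 ± 0.21, adjusted p = 0.0356, and 0.103 without the block), the synaptic vesicle gene Snap91 (−1.79 ± 0.25) and the G-protein subunit Gng3 (−1.37 ± 0.18), which lost their calls in the same way. These genes lie outside the naming rule and were chosen after their values were seen.

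The noncoding gene E030003E18Rik (2.67 ± 0.25) lies next to Aldh1a1, and both were higher in ventral tissue. G630016G05Rik (2.58 ± 0.17), also higher in ventral tissue, lies next to the homeobox gene Meis2, which did not pass (1.35 ± 0.23, adjusted p = 0.0856). Gata6os, next to Gata6, did not pass either (1.80 ± 0.27, adjusted p = 0.0653). Dbh, a catecholamine enzyme of sympathoadrenal cells, differed between arrays of one tissue, at 9.55, 9.66 and 6.75 on dorsal arrays 1 to 3 and 5.44, 8.13 and 8.59 on ventral arrays 1 to 3. The sympathoadrenal list was called lower in ventral tissue without replicate 3 (camera, adjusted p = 0.000381) and higher without replicate 1 (0.0377), and with an estimated correlation in neither (0.557 and 0.742).

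Trac and Traj11 were higher in ventral tissue by 6.23 and 6.24 (log2), with dorsal means below the brightness filter (3.58 and 3.70), so that the size of the difference in transcript is uncertain. T cells in the ventral captures are argued against by a list of 23 T-cell genes, 6 of which passed the brightness filter. The median log2 fold change of the 23 was −0.0119 (95% bootstrap interval over genes −0.132 to 0.0499), and the highest value was 0.57 for Ptprc. The other members lie below the filter, where a small rise could be missed, so a few T cells are not excluded. A transcript holding J and C but no V segments may account for the pattern, but the V segments cannot decide it. The median over 45 V segments was 0.00067 (−0.0539 to 0.116), level as predicted for such a transcript, with Trav7-3 highest at 0.55. However, only 6 of them passed the brightness filter, and the median would also stay level if only a few V segments rose. The median over the 56 J segments other than Traj11 was 0.149 (0.0699 to 0.254), with 6 past the filter and Traj18 highest at 1.77. Cross-hybridisation of another ventral transcript to both probe sets, and a difference between the tissues themselves, stay open and untested.

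Saa1 and Saa2 were higher in dorsal tissue, and they may share signal, so they count as 1 observation. Liver cells in the dorsal captures are argued against by 25 abundant hepatocyte genes, 15 of them past the brightness filter. The median log2 fold change over the 25 was 0.296 (−0.0399 to 0.482). Its sign carries no weight, since on replicate 3 these genes rose by a median of 3.49 in ventral and 2.99 in dorsal tissue. On dorsal 1 and 2, where Saa2 was highest, Afp was at 3.88 and 4.82, against 10.99 on dorsal 3. An acute-phase response in dorsal tissue stays open. The median over 21 genes of that response was 0.0742 (−0.110 to 0.135), but only 5 of these passed the brightness filter, and they ran from −1.14 for Ptx3 to 0.59 for Il1r1, so the median does not decide. On dorsal 3, which held the liver-like signal described next, Saa2 was the lowest of the dorsal arrays, at 6.09 against 8.37 and 8.52. A difference between the tissues that involves these genes alone stays open and untested.

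On both replicate 3 arrays Afp, Ttr, Apoa1 and Alb were high, with Ttr at 9.33 in dorsal and 10.26 in ventral tissue. In both tissues 25 genes were at least 2 (log2) above the mean of replicates 1 and 2, including S100g and Cubn of the yolk sac list (by 5.16 and 3.79 in dorsal, 6.24 and 5.32 in ventral tissue), and 0 were as far below. Fetal liver RNA may be present on both arrays, since the median of 24 fetal liver genes was 1.00 higher (0.257 to 2.47) in dorsal and 1.28 higher (0.551 to 3.39) in ventral tissue, the first only just past the value of 1 set beforehand. Yolk sac RNA cannot be told apart from it, with medians of 0.537 (0.0902 to 1.16) and 1.11 (0.575 to 2.45) over 23 genes, 0 of them on the liver list, because the yolk sac also makes several secreted proteins of the liver, and the highest rise on its list (S100g, 6.24) exceeds that on the fetal liver list (Fgg, 5.05). The rise was larger in ventral than in dorsal tissue for some genes (Apoa4, 5.77 against 3.18; Apoa1, 5.60 against 3.40), so it can enter the comparison of the tissues for these genes. Camera with its preset correlation called the hepatocyte and gut endoderm list higher in ventral tissue without replicate 1 (adjusted p = 0.0112) and without replicate 2 (0.000943), and with an estimated correlation in neither (0.757 and 0.598). No biological explanation was tested.

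For Iigp1, an interferon response and a signal shared with its gene family were also tested, and both were set aside after their results were seen, to keep to 3 patterns. The median over 33 interferon-response genes was 0.0724 (−0.00554 to 0.152), and over 10 other members of the immunity-related GTPase family it was 0.250 (−0.207 to 0.486), with a highest value of 0.91 for Irgm1. Of these genes 6 and 0 passed the brightness filter, and nothing else was tested.

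Other splits of the 6 arrays are too few to reach a share under 0.05. The real split gave 62 genes with the block and the highest of the other splits that part all 3 pairs gave 0, so 1 of 4 splits gave as many. Without the block the real split gave 59 and the highest of the others 0, so 1 of 10 splits gave as many.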
